A study of Mus musculus with 21 samples.

How the data were processed

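RNA from the lungs of 21 C57BL/6 mice was measured with 1 library per animal, 3 animals in each of 7 groups. The groups were saline, 10% ethanol, PG at 826 and 1100, and VEA at 3.12, 6.25 and 12.5. Per the labels, 500 ng of total RNA went into each Lexogen QuantSeq 3′ library. The labels name Bowtie2, bedtools and the assembly mm10 for the processing, with no versions given. The files deposited by the authors hold counts per gene symbol, 1 file per library, which were checked to be whole numbers. Each file has 23282 rows and 23238 distinct symbols, and counts of the 35 symbols on more than 1 row were summed. Gene coordinates were taken from GENCODE release M21 for GRCm38, a choice made here because the annotation used for counting is not named.

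Total counts were 8778028 to 11783151 per library, and 14843 to 15992 genes had at least 1 count. A level of 5 CPM stands for 43.89 to 58.9 counts. Between animals of 1 group the chi-square per degree of freedom was 8.14 to 40.48, where counting error alone gives about 1, so tests rest on the spread between animals. Sex was checked from sex-linked genes, and all 21 libraries carried Y-linked transcripts.

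Differences were tested with edgeR 4.0.16 in R 4.3.3, with the data.table package (version 1.17.8) for reading files. Genes were filtered by group with filterByExpr, which left 14727, libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group and robust spread was fitted to all 21 libraries. It had 14 residual degrees of freedom, a common dispersion of 0.0567 and a biological coefficient of variation of 23.81%. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested in each of 10 comparisons. These were each dose against its control, ethanol against saline, the doses of an agent against each other, the VEA trend over dose with centred doses as weights, and the VEA 12.5 effect minus the PG 1100 effect. Log2 fold changes are those of the edgeR model, and CPM are scaled by TMM. The SE given with a log2 fold change was derived as its absolute value over the square root of the F statistic of its test. List averages per library are of log2 CPM with a prior count of 2.

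Of 33 gene lists written from general knowledge, 32 were tested with camera (limma 3.58.1, preset correlation 0.01, at least 4 tested members) on voom log2 CPM with an offset of 0.5, in 7 comparisons. The list of basal and squamous cells had fewer than 4 members past the count filter and was not tested. These lists and the sex-linked genes hold 486 symbols, of which 477 are in the files. P values were adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it, and member counts are given over all genes and adjusted over the list alone. Agreement between doses was described by correlation and shared calls across genes, with 20 simulations of unchanged groups.

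Genes were named by a rule. Among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups compared, the 10 largest rises and 10 largest falls were named. For the difference between agents, the trend and the comparisons of doses, 5 each way were named, and overlap was allowed for the difference and the trend. Where a direction had no called gene, the 5 smallest p values were named as not having passed. Up to 4 members were named per list. Unnamed gene models, microRNA, small nucleolar, Rn-numbered and immunoglobulin variable symbols were left out of the naming and kept in the tests. For genes with no count in a group, a floor of 3 counts over the group was used, and for 1 to 3 counts a 95% counting interval of the ratio is given.

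The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no low-count filter, only the groups compared in the fit, a log2 fold change of at least 1, ranks of dose for the trend, and leaving out each animal in turn. Added after seeing the data were a fit without the 3 libraries with the fewest detected genes (saline 8, ethanol 13, VEA 65), a fit without Rn45s and 6 haemoglobin symbols, and the agreement for genes at 5 CPM or more. The tools were tested on simulated data of the size of VEA 12.5 against ethanol, with 14727 genes of which 200 were changed. The changed genes were drawn only from genes above a minimum mean count, in a single simulated data set. Recovery for genes with fewer counts was not measured. edgeR recovered 16.42%, 46.27% and 81.82% of changes of 1.5, 2 and 4 times with 4% false calls. DESeq2 recovered 25.37%, 50.75% and 87.88% with 10.66% false calls, and limma-voom 17.91%, 47.76% and 77.27% with 3.06%. No library was left out of the main results.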

Results

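Gene expression was measured in the lungs of 21 C57BL/6 mice by 3′ end RNA sequencing, in which reads come from the end of each transcript. The animals received 50 µL into the trachea daily for 14 days and were killed on day 15, and lung tissue was taken after bronchoalveolar lavage. Propylene glycol (PG), a solvent of e-cigarette liquids, was given at 826 or 1100 and compared with saline. Vitamin E acetate (VEA), an oily additive, was given at 3.12, 6.25 or 12.5 and compared with 10% ethanol. The sample labels give these doses in mg/kg, while the series description gives the same numbers in mg/mL, so only the numbers are used here. The labels name 10% ethanol as the VEA control and do not state what VEA was given in, so each VEA change is a difference from the 10% ethanol animals. Each of the 7 groups held 3 animals, and each library came from 1 animal. Total counts ranged from 8778028 to 11783151 per library. Ribosomal Rn45s took 14.59% to 26.07% of the counts and haemoglobin transcripts took 4.06% to 13.75%. Levels are given as CPM, counts scaled to the TMM-adjusted library total (mean ± SD, n = 3), and changes as log2 fold change ± SE. Positions are on the mouse assembly GRCm38. Intervals and floors given with low counts cover counting error only. Amd1 and Amd2, haemoglobin genes, and Ear6, Ces1f, Ces1g, Gsta2 and Ly6i have close relatives, and reads shared between relatives were not tested. Among the genes given as the largest rises and falls against a control and between the PG doses, the groups of 3 did not overlap in CPM, which chance gives for 10% of genes.

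PG at 826 was compared with saline to ask what the lower dose changed in the lung. A small set of genes differed: 14 rose and 6 fell among 14727 tested. Retnla, a secreted marker of alternatively activated macrophages (chromosome 16, 48842551 to 48844461), rose by 2.06 ± 0.36, from 95.7 ± 28.2 to 399.8 ± 186 CPM. Fkbp5, a co-chaperone of steroid receptors (chromosome 17, 28399094 to 28517527), rose by 2.04 ± 0.27 (adjusted p = 9.56e-05), from 5.89 ± 3.10 to 24.0 ± 4.84 CPM. The clock genes Dbp (1.97 ± 0.34), Per1 (1.76 ± 0.31) and Nr1d1 (1.07 ± 0.23) also rose. Tff2, which encodes a secreted mucosal peptide, fell by 2.46 on the log2 scale (SE 0.41), from 14.0 ± 0.322 to 2.51 ± 1.43 CPM, and Asgr1, a subunit of the asialoglycoprotein receptor, by 1.99 (SE 0.32).

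Other genes that rose after PG 826 were Sema7a (1.39 ± 0.24), Lox (1.07 ± 0.20), Tmem106a (1.07 ± 0.23), Zfp598 (0.97 ± 0.22) and Col1a1 (0.93 ± 0.20). Those that fell were Vpreb3 (-1.47 ± 0.27), Mak (-1.25 ± 0.27), Gstm2 (-0.72 ± 0.15) and Pttg1 (-0.66 ± 0.14). Of the 32 gene lists tested, camera with a preset correlation called 12, and none of these held with an estimated correlation, where the smallest adjusted p was 0.146. In the circadian clock list 3 of 14 members rose; adjusted over the list alone, 6 rose and 1 fell (adjusted p = 0.245 with an estimated correlation). Its E-box driven members were also higher in ethanol than in saline animals (median 0.60, none past the test). In the matrix and fibrosis list 2 of 19 members rose, Lox and Col1a1, and 6 did so adjusted over the list alone (adjusted p = 0.146 with an estimated correlation). The alveolar macrophage list had 1 riser of 15 members, Chil3 (0.93 ± 0.16), and the type 2 and eosinophil list 1 of 11, Retnla; adjusted over the list alone the counts were 4 and 3 (both adjusted p = 0.146 with an estimated correlation). No member of the club cell and ciliated cell lists passed over all genes, and 5 of 11 and 5 of 15 were lower adjusted over the list alone (adjusted p = 0.173 and 0.188 with an estimated correlation). Among them Scgb1a1, the main secretory protein of club cells, was 55110 ± 7581 CPM after saline and 38580 ± 1491 CPM after PG 826 (-0.51 ± 0.15). No member of 5 further called lists passed over all genes: surfactant and type II cells (higher), lipid-handling macrophages (higher), heart and skeletal muscle, erythroid, and xenobiotic metabolism (each lower), with adjusted p = 0.335, 0.526, 0.245, 0.245 and 0.146 with an estimated correlation. The same held for immediate early genes (lower, adjusted p = 0.526 with an estimated correlation). Adjusted over the list alone, 2 lipid-handling genes were higher, and 3 xenobiotic and 3 immediate early genes were lower. The count of 20 genes rested on single animals: it was 5 without saline 8, 10 without saline 10, 12 without PG 23, 11 without PG 25 and 120 without saline 6, and it was 78 with DESeq2. Fkbp5, Dbp and Asgr1 passed under all 13 alternatives, and Tff2 under all but limma-voom (adjusted p = 0.0573, range 2.15e-12 to 0.0573). Calls of the other 12 largest changes ended without saline 8, and some also without saline 10 or PG 22, 23 or 25. Over the alternatives their adjusted p ranged from 1.2e-36 to 0.311 for Retnla, 6.54e-07 to 0.0768 for Per1, 3.4e-07 to 0.0757 for Sema7a, 2.12e-05 to 0.145 for Lox, 7.59e-05 to 0.340 for Nr1d1 and 0.00266 to 0.244 for Tmem106a. It ranged from 0.00628 to 0.380 for Zfp598, 6.54e-07 to 0.365 for Col1a1, 0.00011 to 0.131 for Vpreb3, 0.00233 to 0.306 for Mak, 0.00113 to 0.183 for Gstm2 and 0.00233 to 0.315 for Pttg1. List calls ended without saline 6 (surfactant 0.0647, lipid-handling 0.161, type 2 0.0609, immediate early 0.207, clock 0.101), saline 8 (type 2 0.0551, erythroid 0.0833, clock 0.0551), saline 10 (surfactant 0.0737) and PG 23 (surfactant 0.366, type 2 0.0598).

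PG at 1100 changed the lung far more widely, with 602 genes higher and 475 lower than after saline (edgeR quasi-likelihood test). The smallest adjusted p belonged to Igf1, a growth factor singled out after its values were seen, which rose by 2.10 ± 0.15 (adjusted p = 6.08e-12), from 34.1 ± 6.50 to 146.5 ± 16.0 CPM. In the matrix list 15 of 19 members rose, and in the endothelial list 8 of 15 fell, calls that held with an estimated correlation. Tnc, a matrix glycoprotein of remodelling tissue (chromosome 4, 63959785 to 64047015), rose by 3.73 ± 0.40 (adjusted p = 9.74e-07), a level 13.3 times that after saline. Spp1, osteopontin (chromosome 5, 104435118 to 104441050), rose by 3.94 ± 0.59, with 142.8, 987.5 and 238.8 CPM in the 3 treated animals against 29.9 ± 12.6 CPM after saline.

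The other largest rises after PG 1100 were in Chl1 (4.41 ± 1.05), Msr1 (3.92 ± 0.55), Ankrd37 (3.57 ± 0.61), Mmp12 (3.52 ± 0.46), Arg1 (3.48 ± 0.60), Ncapg (3.33 ± 0.64), Retnla (3.24 ± 0.37) and Ccl8 (3.17 ± 0.46). The largest falls were in Ankrd63 (-4.00 ± 0.53), Asgr1 (-3.24 ± 0.35), Cacna2d4 (-2.51 ± 0.50), Sox18 (-2.47 ± 0.65), Tmeff2 (-2.43 ± 0.48), Sox11 (-2.37 ± 0.19), Ces1f (-2.23 ± 0.47), Cox8b (-2.23 ± 0.40), Pon1 (-2.22 ± 0.31) and Fabp1 (-2.12 ± 0.45). Sox18 is a transcription factor of vessel development, and Pon1 encodes paraoxonase. In the fit of only the groups compared Spp1, Arg1, Fabp1 and Ankrd37 did not pass (adjusted p = 0.175, 0.183, 0.109 and 0.0558, the highest of ranges that start at 3.44e-113, 2.35e-20, 3.56e-11 and 3.7e-19). Chl1 lost its call without saline 8 (0.0577), saline 10 (0.0609) or PG 28 (0.056), with a range from 4.73e-12 to 0.0609, and Sox18 without saline 6 (0.111), saline 10 (0.0616), PG 28 (0.157) or PG 30 (0.0963), with a range from 3.66e-20 to 0.171.

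Of 19 lists called after PG 1100, 10 held with an estimated correlation. In the matrix and fibrosis list 15 of 19 members rose and none fell (18 adjusted over the list alone), among them Fn1 (2.04 ± 0.21), Col1a1 (2.02 ± 0.20), Eln (2.07 ± 0.23) and Lox (1.59 ± 0.20), which encode fibronectin, a collagen I chain, elastin and a crosslinking enzyme. In the lipid-handling macrophage list 15 of 22 members rose and 1, the fatty acid receptor Cd36 (-0.45 ± 0.13), fell, the same counts as adjusted over the list alone; Lipa (1.46 ± 0.18), Cd63 (1.04 ± 0.14) and Gpnmb (3.02 ± 0.49) were among the risers. The recruited monocyte and macrophage list had 7 risers of 14 (9 adjusted over the list alone), such as C1qa (1.53 ± 0.17) and Ms4a7 (2.31 ± 0.35). In the alveolar macrophage list 8 of 15 rose, led by Chil3 (1.18 ± 0.16), and Krt79 fell (-0.91 ± 0.25); 9 rose and 1 fell adjusted over the list alone. The type 2 and eosinophil list had 5 risers of 11 by either adjustment over all genes or adjusted over the list alone, including the chemokines Ccl8 and Ccl17 (0.87 ± 0.22).

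Epithelial lists moved apart after PG 1100. Surfactant and type II cell genes rose in 7 of 13 (10 adjusted over the list alone), with Sftpd at 1.16 ± 0.15 and Muc1 at 1.02 ± 0.14. Transitional alveolar epithelium genes rose in 5 of 15 (10 adjusted over the list alone), with Cdkn1a at 0.74 ± 0.16 and Sfn at 0.81 ± 0.22. Club cell genes fell in 5 of 11 by both adjustments, over all genes and adjusted over the list alone. Scgb1a1 fell by 1.24 on the log2 scale (SE 0.15), to 23290 ± 3958 CPM, and Cyp2f2 by 1.34 (SE 0.20). Ciliated cell genes fell in 5 of 15 (8 adjusted over the list alone), such as the axonemal dynein Dnah5 (-1.52 ± 0.32), with adjusted p = 0.104 with an estimated correlation. Endothelial genes fell in 8 of 15 (12 adjusted over the list alone), with the vascular growth factor receptor Kdr at -1.18 ± 0.16 and Tek at -1.02 ± 0.14. Xenobiotic metabolism genes fell in 6 of 11 and none rose; adjusted over the list alone, 8 fell and 1 rose. Examples were Fmo1 (-1.52 ± 0.16) and Cyp4b1 (-1.38 ± 0.17).

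The remaining lists called after PG 1100 were lost with an estimated correlation. Cell cycle genes rose in 10 of 17 (13 adjusted over the list alone), for example Cdc20 (1.43 ± 0.31), with adjusted p = 0.120 with an estimated correlation. MHC class II and dendritic cell genes rose in 6 of 14 (adjusted over the list alone, 6 rose and 1 fell), with Cd74 at 0.68 ± 0.16 and adjusted p = 0.0843 with an estimated correlation. Cholesterol synthesis genes rose in 3 of 19 (5 adjusted over the list alone), with Cyp51 at 0.80 ± 0.19 and adjusted p = 0.126 with an estimated correlation. Smooth muscle and pericyte genes rose in 2 of 10 (3 adjusted over the list alone), Cspg4 and Higd1b, with adjusted p = 0.218 with an estimated correlation. Erythroid genes fell in 6 of 8 (also 6 adjusted over the list alone), with adjusted p = 0.0810 with an estimated correlation, and haemoglobin took 4.54% to 5.54% of counts against 6.49% to 13.75% after saline. Immediate early genes fell in 3 of 11 (7 adjusted over the list alone), led by Dusp1 (-1.58 ± 0.18), with adjusted p = 0.0810 with an estimated correlation. In the heart and skeletal muscle list Tnni3 fell (-1.37 ± 0.38), and in the adipocyte list Cox8b did, with adjusted p = 0.135 and 0.374 with an estimated correlation. Each was also the only member to pass adjusted over the list alone. The count of 1077 genes became 547 without PG animal 28 and 444 in the fit of only the groups compared. Without single libraries the smooth muscle call ended (saline 8 0.106, PG 27 0.0811), and so did the adipocyte call (saline 10 0.378, PG 28 0.356).

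**Figure D1:**
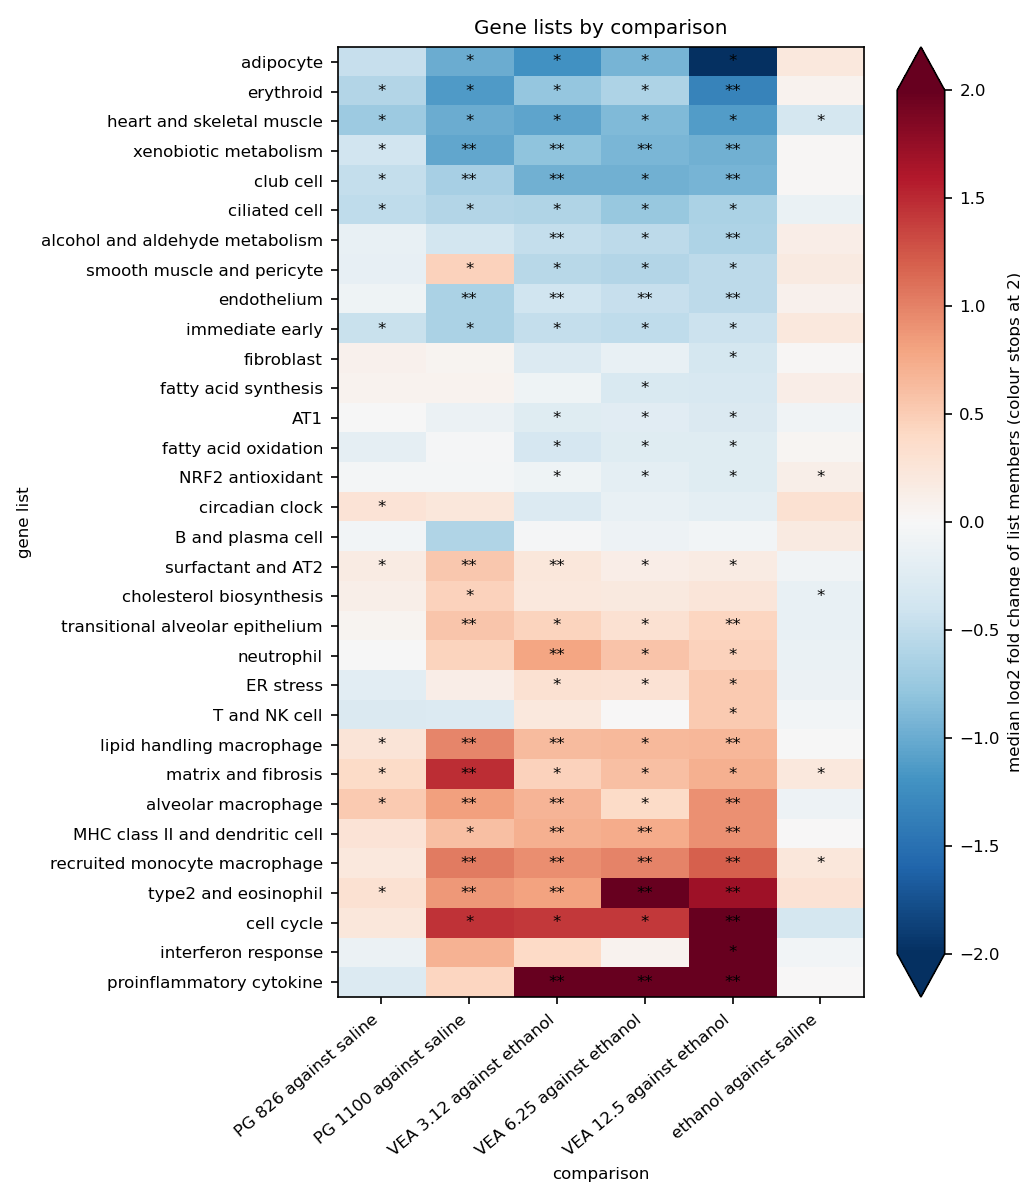
Median log2 fold change of each of the 32 gene lists (vertical axis) in the 5 comparisons with a control and in ethanol against saline (horizontal axis), on a color scale that stops at 2 either way. A single asterisk marks a camera call at the preset correlation and a double asterisk a call that also held with an estimated correlation, of which there are 10 after PG 1100 and 13 after VEA 12.5.

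The PG doses were also compared directly. PG 1100 differed from PG 826 in 818 genes, 419 higher and 399 lower, and Igf1 again had the smallest adjusted p (4.12e-12). Rnu12, a small nuclear RNA, was higher by 4.98 ± 1.38, Arg1 by 3.67 ± 0.61, Ankrd37 by 3.62 ± 0.61, Spp1 by 3.45 ± 0.57 and Cep55 by 2.98 ± 0.80. Ankrd63 (-3.62 ± 0.53), Sox18 (-2.77 ± 0.65), Tmeff2 (-2.48 ± 0.48), Cacna2d4 (-2.21 ± 0.50) and Fabp1 (-1.996 ± 0.44) were lower. Igf1 itself was 33.6 ± 4.93 CPM after PG 826 and 146.5 ± 16.0 CPM after PG 1100. The count depended on animals 27, 28 and 25: it was 1458, 259 and 342 without each, and 425 in the fit of only these 2 groups. Rnu12 lost its call without PG 22 (0.107), 25 (0.159), 28 (0.0828) or 30 (0.0746), with a range over alternatives from 0.000185 to 0.159. Cep55 lost it without PG 22 (0.0885), 23 (0.144), 25 (0.175) or 28 (0.193), with a range from 3.86e-10 to 0.193. Sox18 lost it without PG 25 (0.119), 28 (0.157) or 30 (0.0793), with a range from 4.54e-25 to 0.162, and Cacna2d4 without PG 28 (0.072, range 8.77e-05 to 0.072). With only these groups in the fit Spp1 and Fabp1 did not pass (0.175 and 0.0976, ranges from 3.35e-91 and 8.08e-10).

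Across all genes, fold changes of the PG doses against saline correlated at r = 0.575, where simulated unchanged groups sharing the saline libraries gave 0.4998; genes are not independent replicates. Restricted to genes at 5 CPM or more, r was 0.480 against 0.499 in the simulation, with a covariance of 0.0732 against 0.0335. Of the genes called at both doses, 11 were higher and 6 lower in both, where 0.572 and 0.194 would be expected for independent comparisons, and none went opposite ways. Both doses were compared with the same 3 saline libraries, which are too few to be divided between them. The comparisons are therefore not independent, and these expected counts are no test of agreement.

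VEA was compared with its 10% ethanol control to ask what each dose changed in the lung. After VEA 3.12, 504 genes rose and 308 fell. Saa3, an acute phase protein (chromosome 7, 46711998 to 46715700), rose by 6.62 ± 0.73, from 6.06 ± 3.08 to 596.8 ± 132.8 CPM, and Cxcl1, a neutrophil chemoattractant (chromosome 5, 90891241 to 90893115), by 4.99 ± 0.49 (adjusted p = 1.34e-08), from 0.505 ± 0.328 to 16.5 ± 1.93 CPM. Slc26a4, the anion exchanger pendrin, had the smallest adjusted p (5.03e-11) and rose by 5.31 ± 0.39. In the xenobiotic metabolism list 8 of 11 members fell, a call that held with an estimated correlation.

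Also among the 10 largest rises after VEA 3.12 were Ear6 (4.53 ± 0.74), Cxcl2 (4.52 ± 0.98), Mmp12 (4.31 ± 0.47), Tnfrsf9 (4.18 ± 0.35), Irg1 (4.07 ± 0.83) and Ly6i (4.06 ± 0.62). Ccl3 had 1 count over the 3 ethanol libraries and 21 over the 3 saline libraries, and its level was 240.2 times that of ethanol after VEA 3.12 (95% counting interval 42.7 to 9525). The largest falls were in Cyp1a1 (-3.98 ± 0.79), Wdr63 (-2.48 ± 0.54), Slc4a1 (-2.48 ± 0.58), Ttc21a (-2.41 ± 0.63), Cep126 (-2.40 ± 0.56), Ces1f (-2.38 ± 0.45), Ces1g (-2.21 ± 0.39), Nqo1 (-1.98 ± 0.41), Gsta2 (-1.94 ± 0.56) and Gdpd2 (-1.80 ± 0.40). Cyp1a1, a dioxin-inducible cytochrome, was at 4.06, 55.3 and 44.0 CPM in ethanol animals 12, 13 and 14, at 5.44 ± 2.99 CPM after saline and at 2.18 ± 0.673 CPM after VEA 3.12. Nqo1 was 14.7 ± 6.76 CPM after ethanol, 5.42 ± 2.18 CPM after saline and 3.69 ± 1.26 CPM after VEA 3.12. With limma-voom Cxcl2, Irg1 and Cyp1a1 did not pass (adjusted p = 0.0805, 0.127 and 0.246, the highest of ranges that start at 2.28e-23, 4.07e-07 and 1.53e-20), and with only the groups compared Cyp1a1 did not (0.153). Gsta2 lost its call without ethanol 13 or 14 or VEA 56, 57 or 59 (range 0.00525 to 0.140), Ttc21a without ethanol 12, VEA 56 or VEA 59 (range 0.0014 to 0.0989) and Gdpd2 without ethanol 12 (0.069, range 0.000182 to 0.069).

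VEA 6.25 raised 517 genes and lowered 332. Slc26a4 again had the smallest adjusted p (4.23e-10), at 4.94 ± 0.39, and Saa3 rose by 6.39 ± 0.73, to 508.6 ± 244.5 CPM. Clca1, a secreted product of mucous cells (chromosome 3, 145003817 to 145032776), rose by 4.96 ± 0.69, from 3.04 ± 2.49 to 94.7 ± 9.19 CPM. Cxcl1 rose by 4.92 ± 0.49, Mmp12, the macrophage elastase, by 4.41 ± 0.47, Cxcl2 by 4.30 ± 0.98, Ear6 by 4.09 ± 0.74, Ly6i by 3.96 ± 0.63 and Tnfrsf9 by 3.95 ± 0.35. Ccl3 was 186.5 times the ethanol level, which rested on 1 count, against 21 after saline (95% counting interval 33.1 to 7408). The largest falls were in Cyp1a1 (-3.91 ± 0.79), Ces1f (-2.94 ± 0.47), Ccdc151 (-2.85 ± 0.59), Nqo1 (-2.44 ± 0.43), Ces1g (-2.43 ± 0.40), Micalcl (-2.42 ± 0.64), Cyp4f15 (-2.34 ± 0.65), Dcdc2a (-2.21 ± 0.61), Rsph4a (-2.08 ± 0.36) and Asgr1 (-2.06 ± 0.32). Ccdc151 and Rsph4a belong to the machinery of motile cilia. Without VEA 65 the calls of Cyp1a1 (0.0528), Micalcl (0.102), Cyp4f15 (0.105), Dcdc2a (0.076) and Cxcl2 (0.0614) ended. Without ethanol 13 those of Micalcl (0.069), Cyp4f15 (0.145), Dcdc2a (0.113) and Cxcl2 (0.0577) did, without ethanol 12 those of Cyp4f15 (0.062), Dcdc2a (0.0628) and Cxcl2 (0.0596), and without VEA 64 those of Micalcl (0.0949), Dcdc2a (0.113) and Cxcl2 (0.0549). Over the alternatives the adjusted p ranged from 7.48e-20 to 0.276 for Cyp1a1, 0.00241 to 0.219 for Micalcl, 0.00373 to 0.362 for Cyp4f15, 0.00025 to 0.242 for Dcdc2a and 5.22e-21 to 0.117 for Cxcl2.

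VEA 12.5 gave the highest count of the comparisons, 807 genes higher and 623 lower. Saa3 rose by 7.48 ± 0.75, to 1083 ± 325.6 CPM, and Cxcl1 by 5.87 ± 0.49 (adjusted p = 1.63e-10), to 30.3 ± 10.9 CPM. Slc26a4 rose by 5.76 ± 0.39 (adjusted p = 4.79e-12), Irg1, which encodes the enzyme that makes itaconate, by 5.49 ± 0.83, Ly6i by 5.32 ± 0.63, Clca1 by 5.27 ± 0.70 and Serpinb9b by 5.09 ± 0.94. Dcstamp, a protein of macrophage fusion, and Rgs16 had no count in the ethanol group and were at least 52.6-fold and at least 47.1-fold higher (floor of 3 counts over the group), while the saline group had 4 and 11 counts. Ccl3 was 468.7 times the ethanol level of 1 count, against 21 after saline (95% counting interval 83.8 to 18540).

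The largest falls after VEA 12.5 were in Asgr1 (-3.01 ± 0.34), Nqo1 (-2.55 ± 0.42), Calml3 (-2.55 ± 0.65), Ces1g (-2.45 ± 0.39), Ces1f (-2.42 ± 0.45), Pon1 (-2.42 ± 0.31), Gsta2 (-2.40 ± 0.57), Sult1d1 (-2.33 ± 0.67), Bex2 (-2.17 ± 0.31) and Micalcl (-2.16 ± 0.62). Pon1 went from 138.0 ± 29.7 to 25.7 ± 3.63 CPM. Calls ended for Dcstamp without ethanol 12, 13 or 14 (range over alternatives 2.8e-07 to 0.0761), Calml3 without ethanol 12 or 13 or VEA 66 or 68 (6.64e-09 to 0.0831), Sult1d1 without ethanol 12 or 13 or VEA 66, 68 or 70 (2.23e-19 to 0.148) and Micalcl without ethanol 13 or 14 or VEA 68 or 70 (0.0038 to 0.132). The counts of called genes also moved with single animals. At 3.12 there were 536 without ethanol 12, 449 without ethanol 13, 434 without VEA 56 and 471 without VEA 59. At 6.25 there were 478 without ethanol 12, 478 without ethanol 13, 427 without VEA 64 and 429 without VEA 65. At 12.5 there were 873 without VEA 70.

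**Figure D2:**
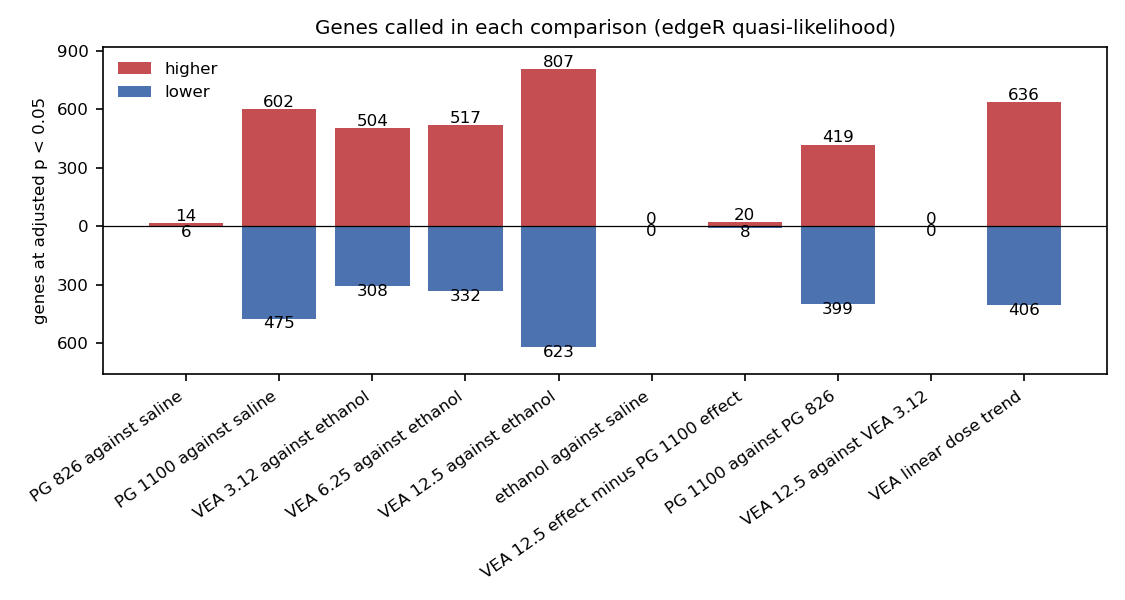
Number of genes called at an adjusted p below 0.05 in each comparison (edgeR), with bars above 0 for genes higher and below 0 for genes lower. PG 826 has 20 genes and PG 1100 has 1077, while the 3 VEA doses have 812, 849 and 1430.

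Inflammatory lists rose at all VEA doses. In the proinflammatory cytokine list 8, 8 and 10 of 14 members rose at 3.12, 6.25 and 12.5 (11, 12 and 11 adjusted over the list alone), and the calls held with an estimated correlation at each dose. Ccl7, a monocyte chemokine, rose by 3.46 ± 0.59, 3.63 ± 0.59 and 4.03 ± 0.59, and Cxcl5 by 3.71 ± 0.55, 3.41 ± 0.55 and 4.08 ± 0.56. In the type 2 and eosinophil list 5, 6 and 7 of 11 rose by both adjustments, also adjusted over the list alone, where 1 fell at 12.5; Ccl17 rose by 2.60 ± 0.22, 2.18 ± 0.22 and 2.49 ± 0.22 and Retnla by 2.78 ± 0.36, 3.02 ± 0.37 and 3.34 ± 0.37. The recruited macrophage list had 7, 7 and 9 risers of 14 (8, 9 and 10 adjusted over the list alone), with C1qa at 1.28 ± 0.17, 1.57 ± 0.17 and 1.92 ± 0.17. The MHC class II and dendritic cell list had 6, 6 and 9 risers of 14. Adjusted over the list alone 9 rose at each dose, and 1 fell at 6.25. Cd74, the class II chaperone, rose by 1.33 ± 0.16, 1.31 ± 0.16 and 1.54 ± 0.16. These lists also held with an estimated correlation at each dose.

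Lipid-handling macrophage genes rose in 11, 9 and 13 of 22 with rising dose (13, 12 and 15 adjusted over the list alone), with Lgals3 at 1.26 ± 0.15, 1.08 ± 0.15 and 1.34 ± 0.15 and Msr1 at 3.75 ± 0.55, 3.88 ± 0.55 and 4.22 ± 0.55. Cd36 fell at 12.5 (-0.40 ± 0.13) and, adjusted over the list alone, 1 member fell at each dose. At 6.25 the list had adjusted p = 0.0672 with an estimated correlation. Alveolar macrophage genes rose in 7, 6 and 8 of 15 and fell in 1, 1 and 2 (9, 6 and 9 rose and 1, 1 and 3 fell adjusted over the list alone). Ctsk rose by 3.48 ± 0.39, 3.31 ± 0.39 and 3.72 ± 0.39, and Cidec, a lipid droplet protein, fell by 1.39, 1.33 and 1.45 on the log2 scale. At 6.25 the list had adjusted p = 0.102 with an estimated correlation. Neutrophil genes rose in 3, 2 and 2 of 11 (3, 2 and 4 adjusted over the list alone), namely Mmp8 (2.63 ± 0.32, 2.48 ± 0.32 and 2.59 ± 0.31), Lcn2 and, at 3.12, Trem1; at 6.25 and 12.5 adjusted p = 0.127 and 0.0666 with an estimated correlation. Cell cycle genes rose in 9, 7 and 14 of 17 (13, 12 and 15 adjusted over the list alone), with Ccnb1 at 2.35 ± 0.47, 1.96 ± 0.48 and 2.63 ± 0.47; at 3.12 and 6.25 adjusted p = 0.0785 and 0.126 with an estimated correlation.

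Interferon response genes were called at VEA 12.5, where 9 of 19 rose (12 adjusted over the list alone), with adjusted p = 0.102 with an estimated correlation. Irf7 rose by 2.89 ± 0.50 and Zbp1 by 2.25 ± 0.38, with wide spread between animals (Irf7 30.4 ± 26.5 CPM). The T and NK cell list was also called at 12.5 with no member past the test by either adjustment (0 adjusted over the list alone), with adjusted p = 0.367 with an estimated correlation. Endoplasmic reticulum stress genes rose in 1, 1 and 2 of 12 (1, 3 and 3 adjusted over the list alone), with Sdf2l1 at 0.94 ± 0.20, 1.06 ± 0.20 and 1.12 ± 0.20 and adjusted p = 0.114, 0.214 and 0.0911 with an estimated correlation.

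Matrix and fibrosis genes rose in 5, 10 and 9 of 19 (8, 13 and 13 adjusted over the list alone), with adjusted p = 0.0976, 0.0717 and 0.0545 with an estimated correlation. Fn1 rose by 0.98 ± 0.20, 1.00 ± 0.20 and 1.34 ± 0.20 and Eln by 1.12 ± 0.22, 1.45 ± 0.22 and 1.38 ± 0.22, while Acta2, smooth muscle actin, fell at 12.5 (-1.05 ± 0.27). Adjusted over the list alone, 1 member fell at each dose. Surfactant and type II cell genes rose in 3, 2 and 5 of 13 (4, 3 and 5 adjusted over the list alone), with Sftpd at 1.24 ± 0.15, 0.94 ± 0.15 and 1.28 ± 0.15; at 6.25 and 12.5 adjusted p = 0.192 and 0.0666 with an estimated correlation. Transitional epithelium genes rose in 2, 2 and 6 of 15 (6, 5 and 7 adjusted over the list alone), with Sfn at 0.77 ± 0.22, 0.89 ± 0.22 and 1.497 ± 0.22; at 3.12 and 6.25 adjusted p = 0.0528 and 0.138 with an estimated correlation. Type I cell genes fell in 2, 1 and 6 of 13, and 1 rose at 12.5; adjusted over the list alone 3, 1 and 7 fell and 1, 1 and 2 rose. Hopx, a type I cell marker, fell by 0.82, 0.65 and 1.07 on the log2 scale (adjusted p of the list = 0.277, 0.291 and 0.200 with an estimated correlation).

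Club cell genes fell in 6, 6 and 7 of 11 (7, 7 and 8 adjusted over the list alone). Scgb1a1 went from 55740 ± 9179 CPM after ethanol to 27730 ± 2046, 28570 ± 2798 and 25310 ± 880.4 CPM, and Cyp2f2 fell (-1.24, -1.24 and -1.55); at 6.25 the list had adjusted p = 0.0622 with an estimated correlation. Ciliated cell genes fell in 7, 6 and 8 of 15 (10, 12 and 11 adjusted over the list alone), with adjusted p = 0.0785, 0.0717 and 0.0726 with an estimated correlation; Sec14l3 fell by 0.60, 0.61 and 0.81 on the log2 scale. Endothelial genes fell in 4, 5 and 5 of 15 (8, 8 and 9 adjusted over the list alone, with 1 riser at 3.12 and 1 at 12.5), with Kdr at -0.89 ± 0.16, -0.83 ± 0.16 and -0.98 ± 0.16, and the calls held with an estimated correlation.

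Xenobiotic metabolism genes fell in 8, 7 and 7 of 11 (9, 10 and 9 adjusted over the list alone) and held with an estimated correlation; Cyp4b1 (-1.34, -1.30 and -1.52) is an example. Alcohol and aldehyde metabolism genes fell in 3, 5 and 4 of 12 (3, 6 and 5 adjusted over the list alone, with 1 riser at 12.5), led by Aldh1a1 (-1.06 ± 0.17, -1.08 ± 0.17 and -1.44 ± 0.18); at 6.25 adjusted p = 0.0672 with an estimated correlation. NRF2 antioxidant genes fell in 4, 5 and 6 of 16, with 1 riser at 12.5, Slc7a11; adjusted over the list alone 6, 5 and 6 fell and 2 rose at 12.5. Gstm1, a glutathione transferase, fell (-0.94, -1.10 and -1.28), and the list had adjusted p = 0.244, 0.136 and 0.166 with an estimated correlation. The NRF2 list average per library was 5.01 to 5.42 after ethanol, 4.85 to 4.99 after saline and 4.85 to 5.13 after the VEA doses. Part of the fall of this list may therefore lie in higher values of the ethanol animals. Fatty acid oxidation genes fell in 1, 1 and 2 of 15 (3, 2 and 4 adjusted over the list alone), Acadm at 3.12, Acaa2 at 6.25 and both at 12.5, with adjusted p = 0.171, 0.102 and 0.159 with an estimated correlation. The fatty acid synthesis list was called lower at 6.25 with no member past the test (0 adjusted over the list alone; adjusted p = 0.335 with an estimated correlation).

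Erythroid genes fell in 1, 2 and 8 of 8 at VEA 3.12, 6.25 and 12.5 (8, 3 and 8 adjusted over the list alone); at 3.12 and 6.25 adjusted p = 0.0785 and 0.127 with an estimated correlation. Haemoglobin took 4.06% to 5.13% of counts after VEA 12.5 and 8.49% to 10.52% after ethanol. The heart and skeletal muscle list was lower at each dose with 0, 0 and 1 members past the test (0, 0 and 4 adjusted over the list alone), Actc1 at 12.5, with adjusted p = 0.198, 0.220 and 0.181 with an estimated correlation. The adipocyte list was lower with 0, 0 and 1 members past it (0, 0 and 5 adjusted over the list alone), Cox8b at 12.5, with adjusted p = 0.198, 0.291 and 0.154 with an estimated correlation. Smooth muscle and pericyte genes fell in 0, 1 and 3 of 10 (2, 2 and 4 adjusted over the list alone), Myh11 at 6.25 and Acta2, Myh11 and Des at 12.5, with adjusted p = 0.246, 0.220 and 0.182 with an estimated correlation. At 12.5 the fibroblast list fell in 4 of 10 members, such as Inmt (-1.02 ± 0.14), and rose in 1, Mfap4, the same adjusted over the list alone (adjusted p = 0.227 with an estimated correlation). Immediate early genes fell in 1, 2 and 3 of 11 and rose in 1, 1 and 2 (1, 4 and 5 fell and 1, 1 and 2 rose adjusted over the list alone); Dusp1 fell while Atf3 rose at each dose, and the list had adjusted p = 0.277, 0.220 and 0.376 with an estimated correlation.

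Single libraries ended list calls after VEA as well, each of a list also lost with an estimated correlation. At 3.12 the losses were type I cell (0.0752), smooth muscle (0.0618) and NRF2 (0.0618) without VEA 59, immediate early (0.0547) without VEA 56, fatty acid oxidation (0.0643), NRF2 (0.0668) and immediate early (0.107) without ethanol 14, smooth muscle (0.108) without ethanol 12 and NRF2 (0.0814) without ethanol 13. At 6.25 they were surfactant (0.0612), type I cell (0.356) and endoplasmic reticulum stress (0.0612) without VEA 63, the stress list (0.103) without VEA 64, fatty acid synthesis (0.285) without VEA 65, fatty acid synthesis (0.0519) and smooth muscle (0.0906) without ethanol 12, heart (0.0666) without ethanol 13, and fatty acid synthesis (0.335) and stress (0.0982) without ethanol 14. At 12.5 they were fatty acid oxidation (0.0562 and 0.0706), T and NK cell (0.157 and 0.438) and immediate early (0.240 and 0.0689) without ethanol 14 and without VEA 68, T and NK cell (0.0789) and fibroblast (0.134) without ethanol 13, fibroblast without ethanol 12 (0.0573) and VEA 70 (0.0571), and immediate early (0.0539) without VEA 66.

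**Figure D3:**
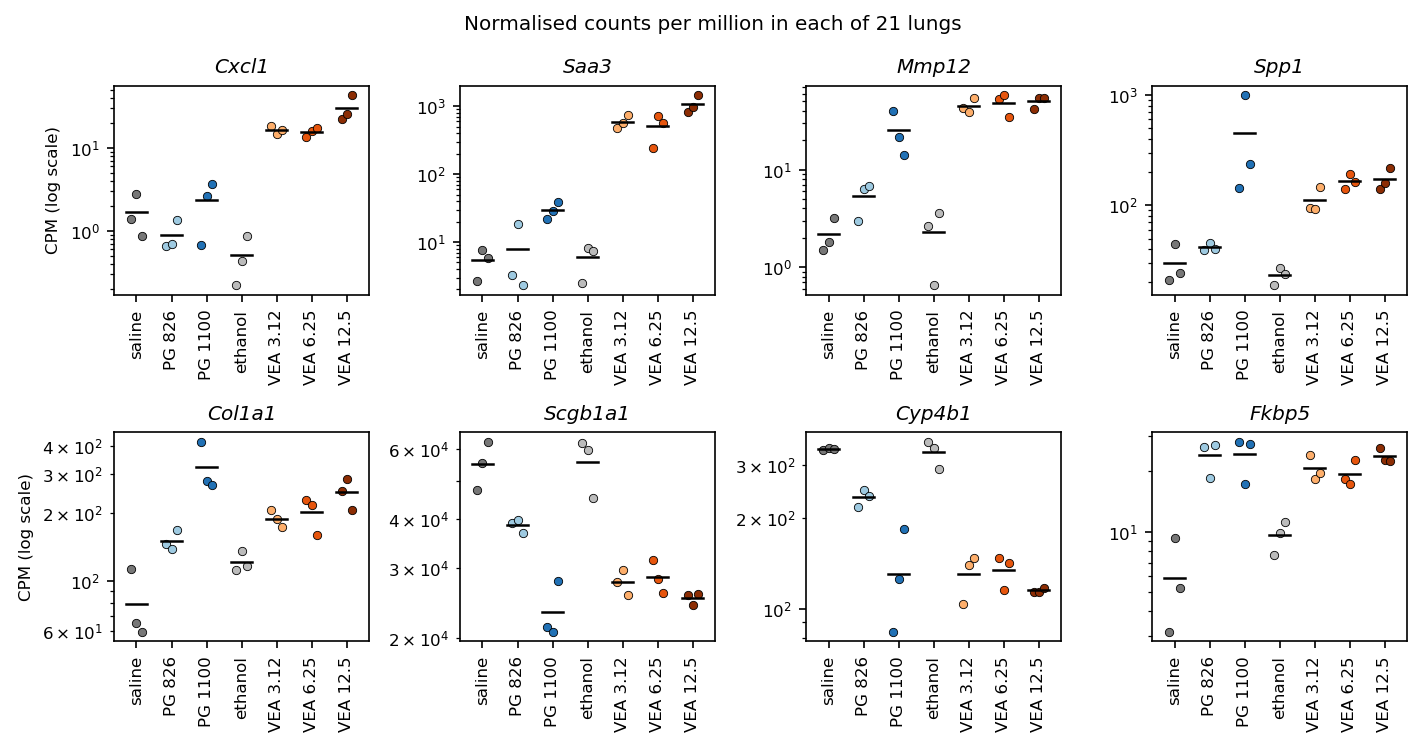
Levels of Cxcl1, Saa3, Mmp12, Spp1, Col1a1, Scgb1a1, Cyp4b1 and Fkbp5 in CPM (vertical log axis) in the 7 groups (horizontal axis), with 1 point per library and a bar at the mean of each group of 3. Saa3 averages 6.06 CPM after ethanol and 1083 CPM after VEA 12.5, and Scgb1a1 averages 55110 CPM after saline and 23290 CPM after PG 1100.

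VEA 12.5 was compared directly with VEA 3.12, and no gene passed with edgeR, where 801 had an unadjusted p below 0.05. DESeq2 called 3 and limma-voom 0, and with no low-count filter edgeR called 60, with only these groups 24, and without VEA animal 66 it called 8. The smallest p values, none of which passed, belonged to Lmnb1 (0.85 ± 0.20), Spi1 (0.73 ± 0.17), Rraga (0.69 ± 0.17), Trim30a (0.81 ± 0.20) and Lgals9 (0.76 ± 0.19) on the higher side. On the lower side they were Synm (-0.79 ± 0.16), Asgr1 (-1.35 ± 0.34), Nes (-0.58 ± 0.15), C1d (-0.62 ± 0.16) and Cped1 (-0.68 ± 0.18). Synm had the smallest adjusted p, 0.261 (range over alternatives 0.00108 to 1), and passed with DESeq2 (0.022). Without VEA animal 66 Trim30a and Lgals9 passed (0.00857 and 0.0489, ranges 0.00108 to 1 and 0.00159 to 1).

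A linear trend over 0, 3.12, 6.25 and 12.5 was called for 1042 genes, 636 rising and 406 falling. With doses exchanged among the VEA animals, 5 of 100 splits called as many, the real grouping included. Slopes in log2 per dose unit were 0.49 ± 0.05 for Saa3 and 0.39 ± 0.03 for Cxcl1 (adjusted p = 6.33e-10). Ethanol counts as dose 0, so a step from ethanol to any VEA dose gives a slope even without an order of the doses. Saa3 was higher than in ethanol by 6.62 at 3.12 and 7.48 at 12.5, and Cxcl1 by 4.99 and 5.87. On the log2 scale most of their change was thus reached at 3.12. Dcstamp, Rgs16 and Ccl3, with at most 1 count in the ethanol group, also rose, and their fitted slopes are not given because they depend on that floor. The steepest falls were in Asgr1 (-0.22 ± 0.03), Cyp1a1 (-0.21 ± 0.06), Calml3 (-0.18 ± 0.05), Nqo1 (-0.18 ± 0.03) and Pon1 (-0.17 ± 0.02). The trend count was 484, 544 and 683 without VEA animals 70, 68 and 66. Cyp1a1 lost its call in 14 of 19 alternatives (range 4.09e-10 to 0.353), among them without any of the 9 VEA libraries or ethanol 13 or 14 (0.0528 to 0.159). Dcstamp lost it in 7 (range 3.24e-07 to 0.117), among them without ethanol 12, 13 or 14 or VEA 68 or 70, and Calml3 in 8 (range 2.19e-07 to 0.143), among them without ethanol 12 or 13 or VEA 57, 66, 68 or 70.

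Fold changes of VEA doses against ethanol correlated across genes at r = 0.741 for 3.12 with 6.25, 0.794 for 3.12 with 12.5 and 0.756 for 6.25 with 12.5, where unchanged groups simulated against the same controls gave 0.497, 0.505 and 0.502. At 5 CPM or more these were 0.860, 0.877 and 0.839, against 0.499, 0.504 and 0.5035 in the simulation. VEA 3.12 and 12.5 shared 412 genes called higher and 223 called lower, with 27.6 and 13.0 expected for independent comparisons, and no gene went opposite ways in any of these pairs. Shared calls between 3.12 and 6.25 were 347 and 173 (expected 17.7 and 6.94), and between 6.25 and 12.5 they were 371 and 221 (expected 28.3 and 14.0). The 3 doses were compared with the same 3 ethanol libraries, so the comparisons are not independent and these expected counts are no test of agreement.

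The controls were compared with each other, and no gene differed between ethanol and saline with edgeR, where 892 had an unadjusted p below 0.05. DESeq2 called 1 gene and limma-voom 0. With no low-count filter edgeR called 17, without saline 6 it called 2 and without ethanol 12 it called 1. The genes with the smallest p, none past the test, were Axin2 (1.47 ± 0.30, adjusted p = 0.234), Cspg4 (1.51 ± 0.35), Cbr3 (0.86 ± 0.21), Dbp (1.31 ± 0.34) and Fbln2 (1.31 ± 0.36) on the higher side. On the lower side they were Kif23 (-1.76 ± 0.39), Rpp30 (-1.26 ± 0.29), Tinag (-0.85 ± 0.21), Papolg (-1.14 ± 0.29) and Mrto4 (-0.93 ± 0.24). Axin2 passed with DESeq2 (0.0048), with no filter (0.0206) and without saline 6 (0.0291), with a range over alternatives from 0.0048 to 0.949. Of the lists, 5 were called: recruited macrophage, matrix and NRF2 genes higher, cholesterol synthesis and heart and skeletal muscle genes lower, each with adjusted p = 0.628 with an estimated correlation. No member of them passed over all genes, and adjusted over the list alone 2 NRF2 genes did. Each of these calls ended without at least 1 of the 6 libraries: without saline 6 recruited macrophage (0.163), cholesterol (0.0823), heart (0.0621) and NRF2 (0.0621), without saline 8 cholesterol (0.121) and matrix (0.0800), and without saline 10 cholesterol (0.096), matrix (0.501) and heart (0.245). Without ethanol 12 the heart call ended (0.855), without ethanol 13 recruited macrophage (0.218), cholesterol (0.0751) and matrix (0.0751), and without ethanol 14 cholesterol (0.241) and heart (0.084).

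The effects of VEA 12.5 and PG 1100, each against its own control, were compared to ask how the agents differ. The difference passed for 28 genes, positive (termed toward VEA here) in 20 and negative (toward PG) in 8. This sign does not tell which agent changed a gene more. Ankrd63, among the 20, fell after PG 1100 (-4.00) and did not pass after VEA 12.5 (-0.96). Cldn10, among the 8, fell after VEA 12.5 (-1.34) and did not pass after PG 1100 (-0.35). With agents exchanged among treated and among control animals, 11 of 100 splits called 28 genes or more, the real grouping included. Among the called genes at 5 CPM or more, the largest differences toward VEA were in Cxcl5 (5.46 ± 0.80), Cxcl1 (5.39 ± 0.68, adjusted p = 3.89e-05), Ly6i (5.19 ± 1.10), Rgs1 (3.62 ± 0.72) and Nup62-il4i1 (3.17 ± 0.56). Cxcl1 changed by 5.87 after VEA 12.5 and by 0.48, not past the test, after PG 1100. It averaged 1.69 CPM after saline and 0.505 CPM after ethanol, not past the test, so part of its difference lies between the controls. Toward PG they were in Col8a1 (-2.67 ± 0.52), Per1 (-2.37 ± 0.44), Acta2 (-1.90 ± 0.37), Tmem252 (-1.71 ± 0.33) and Amd2 (-1.67 ± 0.33). The count of 28 was 48 without saline 6, 17 without saline 8, 12 without ethanol 13, 18 without ethanol 14, 44 without PG 28, 13 without VEA 68 and 16 without VEA 70. Per1 was also 1.06 higher in ethanol than in saline animals, not past the test, so part of its difference lies between the controls. Over the alternatives Per1 kept its call, while the adjusted p reached 0.0785 for Cxcl1 (limma-voom, range from 4.56e-16), 0.0969 for Cxcl5 (without the 3 libraries with the fewest detected genes, range from 8.87e-49) and 0.183 for Nup62-il4i1 (limma-voom, range from 6.34e-05). Single libraries ended the calls of Ly6i (9 of 12, 0.0618 to 0.509), Acta2 (10 of 12, 0.0702 to 0.140), Amd2 (9 of 12, 0.0556 to 0.0842) and Col8a1 (6 of 12, 0.0618 to 0.0844). They also ended those of Rgs1 (ethanol 13 0.0653, VEA 68 0.0525) and Tmem252 (ethanol 13 0.0824, PG 27 0.0507).

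Camera called 21 lists for the difference between the agents, 11 toward VEA and 10 toward PG, and none held with an estimated correlation (smallest adjusted p = 0.0593). Here too the direction is the sign of the VEA effect minus the PG effect, not the agent with the larger change. The endothelial list, toward VEA, fell after both agents, and the alcohol and aldehyde list, toward PG, fell after VEA 12.5. Toward VEA, the proinflammatory cytokine list had 3 of 14 members past the test (10 adjusted over the list alone), Cxcl1, Cxcl5 and Tnf. Tnf had 1 count in the ethanol group and 176 after VEA 12.5, and 17 in the saline group and 2 after PG 1100, so its difference rests on both arms and on unequal controls. Toward PG, the matrix and fibrosis list and the smooth muscle and pericyte list had 1 member each past the test (6 and 6 adjusted over the list alone), Acta2 in both. These 3 lists each had adjusted p = 0.0593 with an estimated correlation. The other lists called toward VEA were MHC class II and dendritic cell, interferon, neutrophil, type 2 and eosinophil, B and plasma cell, T and NK cell, endothelium, endoplasmic reticulum stress, cell cycle and immediate early genes, with adjusted p = 0.142, 0.209, 0.182, 0.182, 0.182, 0.211, 0.209, 0.211, 0.397 and 0.209 with an estimated correlation. Over all genes 1 type 2 member (Ccl17), 1 stress member (Ddit3) and 1 immediate early member (Atf3) passed. Adjusted over the list alone the counts were 5, 1, 1, 3, 1, 1, 2, 3, 0 and 1. Those called toward PG were surfactant, fatty acid synthesis, fatty acid oxidation, fibroblast, erythroid, NRF2, alcohol and aldehyde, and clock genes, with adjusted p = 0.182, 0.209, 0.209, 0.315, 0.488, 0.179, 0.209 and 0.209 with an estimated correlation. Of these only the clock list had a member past the test over all genes, Per1; adjusted over the list alone 3 clock, 2 NRF2 and 1 fatty acid synthesis genes were lower and 1 fatty acid synthesis gene was higher. Leaving out 1 library ended calls in 12 of these lists, with each of the 12 libraries of the 4 groups ending at least 1 of them, and the adjusted p of the lost calls ran from 0.0516 (stress list without saline 6) to 0.923 (erythroid without saline 6).

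Effects of the agents also overlapped. Fold changes of PG 1100 and VEA 12.5, which share no library, correlated across genes at r = 0.390, and at 0.608 for genes at 5 CPM or more, where simulated unchanged groups gave -0.00363 for all genes. Both agents raised 304 genes and lowered 216, with 33.0 and 20.1 expected for independent comparisons. Both comparisons come from the same fit with a shared estimate of the spread of each gene, so these expected counts are no test of agreement. Among the genes called for both agents only Tmem252 went opposite ways, higher after PG 1100 (0.99) and lower after VEA 12.5 (-0.72).

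**Figure D4:**
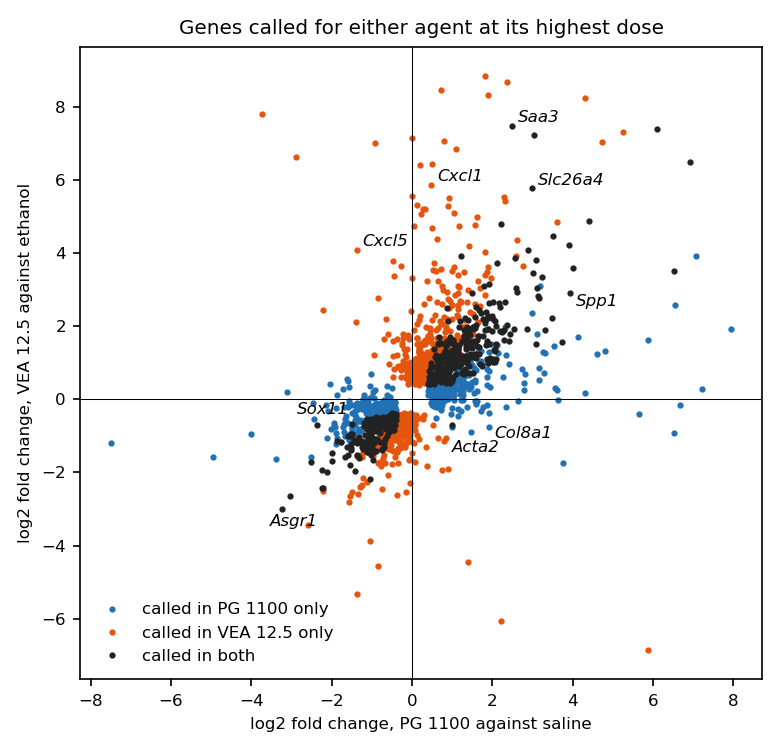
Log2 fold change after PG 1100 (horizontal axis) and after VEA 12.5 (vertical axis), each against its own control, for the genes called in either comparison, colored by where they were called. The named points include Cxcl1, at 0.48 after PG 1100 and 5.87 after VEA 12.5, and Acta2, at 0.85 and -1.05.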

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

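The splits of the samples given here were chosen as tests only after the results were seen. The effects of VEA 12.5 and PG 1100, each against its own control, differed by a test of the difference itself in 28 genes. The values by which the named genes differ (VEA minus PG, log2) are 5.46 for Cxcl5, 5.39 for Cxcl1, 5.19 for Ly6i, 3.62 for Rgs1 and 3.17 for Nup62-il4i1. Part of the Cxcl1 value lies between the controls, at 1.69 CPM after saline and 0.505 CPM after ethanol. Toward PG they are -2.67 for Col8a1, -2.37 for Per1 (of which 1.06 lies between the controls, ethanol being higher), -1.90 for Acta2, -1.71 for Tmem252 and -1.67 for Amd2. Of 100 splits of the 12 libraries, the real grouping included, 9 gave 28 or more genes, with 1184 as the highest of the others. That split set 5 of the 6 treated animals on 1 side of the contrast, so its calls follow treatment, and such splits are no test of the difference between agents. When only agents were exchanged, among treated and among control animals, 11 of 100 splits, the real grouping included, gave 28 or more genes. Chance can therefore not be excluded for the count. The highest of these other splits called 217 genes, and what sets its animals apart was not tested. Amd1 (-1.61) also passed; its sequence is close to that of Amd2, and reads shared between the 2 genes were not tested.

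Among the other genes with a passing difference, Gdf15 rose with both agents (3.91 after VEA 12.5, 1.21 after PG 1100), and so did Slc26a4 (5.76 and 2.98) and Tnfrsf9 (4.78 and 2.23), so these differ in size and not in direction. Col8a1 (1.91), Adamts1 (1.14) and Amd2 (1.63) rose after PG 1100 and did not pass after VEA 12.5. Sox11 fell with both (-0.71 after VEA 12.5, -2.37 after PG 1100). No biological explanation for these differences was tested, since agent and control change together between the arms, and the labels do not state what VEA was given in.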

How the results depend on the processing

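Fits without the 3 libraries with the fewest detected genes and without Rn45s and haemoglobin were chosen as tests only after the results were seen; the other alternatives were fixed before the data were examined. None of the results reversed. For 146 gene results under 2018 alternatives, 1746 kept direction and side of the threshold, 251 lost a call, 21 gained one, and 81 results held throughout. For 136 list calls under 1350 alternatives, 1098 held and 252 were lost, and 41 calls held throughout; an estimated correlation kept 41 of the 136, fry 78 and RLE size factors 136. Of 153 alternatives for the 10 counts of called genes, 98 stayed within 1.5 times. In the others, DESeq2 called 78 genes for PG 826, 1 for ethanol against saline, 103 for the difference between agents and 3 for VEA 12.5 against 3.12. With no low-count filter these counts were 162, 17, 198 and 60. Limma-voom called 8 for the difference. With only the groups compared there were 444 for PG 1100, 14 for the difference, 425 for PG 1100 against 826 and 24 for VEA 12.5 against 3.12. Without the 3 libraries there were 6 for PG 826, 539 for VEA 3.12, 316 for VEA 6.25 and 12 for the difference. The cause was not tested for these. A log2 fold change of at least 1 leaves by construction fewer genes: 12 for PG 826, 477 for PG 1100, 358, 371 and 638 for VEA 3.12, 6.25 and 12.5, 268 for PG 1100 against 826 and, for the change over the range from 0 to 12.5, 438 for the trend. Leaving out 1 animal gave 5 to 120 genes for PG 826, 547 to 1207 for PG 1100, 434 to 621, 427 to 811 and 873 to 1090 for VEA 3.12, 6.25 and 12.5, 0 to 2 for ethanol against saline, 12 to 48 for the difference, 259 to 1458 for PG 1100 against 826, 0 to 8 for VEA 12.5 against 3.12 and 484 to 1078 for the trend; these fits hold fewer samples. Rnu12 has no adjusted p in DESeq2. No paired analysis was possible because each animal number occurs once. Depth limits genes with few counts, and a level of 5 CPM stands for 43.89 to 58.9 counts.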

Other observations

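Single immune and antioxidant genes also changed. Jchain, which joins IgA and IgM chains in plasma cells, rose after VEA 3.12, 6.25 and 12.5 (1.97, 2.35 and 2.57) and did not pass after PG 1100. Lcn2, a siderophore-binding protein of neutrophils and epithelium, rose after PG 1100 (2.57) and after the VEA doses (3.18, 2.78 and 3.85). After PG 1100 the NRF2 antioxidant list was not called, with 3 members higher and 1 lower and a median (-0.03) and mean (0.20) of opposite sign. Its members Hmox1 (2.33), Slc7a11 (1.63) and Gclc (0.69) rose while Gstm1 (-0.99) fell. Bhlhe41, a transcriptional repressor, rose after the VEA doses (1.51, 1.32 and 1.54) and did not pass after either PG dose. These genes were chosen after their values were seen, and the difference between the VEA 12.5 and PG 1100 effects did not pass for Jchain, Lcn2, Bhlhe41 or Hmox1.

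All tests below were chosen only after the results were seen. After PG 826 the clock genes Per1, Dbp and Nr1d1 and the glucocorticoid target Fkbp5 rose. Time of day at killing may explain the clock genes: the E-box driven members have a median of 1.01 and the opposite-phase members one of -0.38, but the latter were about as low after VEA 3.12, 6.25 and 12.5 (-0.33, -0.36 and -0.31) without a higher E-box median (-0.24, 0.01 and -0.15), so they do not single out a shift of phase. The E-box medians against saline are also above 0 for PG 1100 (0.80) and ethanol (0.60), with opposite-phase medians of -0.85 and -0.33. The 3 saline libraries have the lowest clock scores of the 21 (-1.05 to -0.68, others from -0.42), so the shift may lie in the saline animals and not in PG. Higher glucocorticoid signalling may also contribute after PG 826: with Fkbp5 left out, 7 of its targets have a median of 0.50, though only 1 passed over all genes. Fkbp5 rose after VEA 12.5 as well (1.32), where the E-box driven members have a median of -0.15 and the 7 targets one of -0.29 (2 rose, 3 fell), so for Fkbp5 there time of day and other causes cannot be told apart; the labels give no times of killing.

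Against ethanol, log2 effects of VEA at 3.12 were nearly as large as at 12.5 among genes called at 6.25. This choice leaves out genes not called at 6.25, and 1430 genes were called at 12.5 against 812 at 3.12. PG 1100 differed from PG 826 in 818 genes. Log2 effects proportional to VEA dose are excluded, since they give a ratio of 0.25 between 3.12 and 12.5. The ratio of mean signed log2 effects was 0.864 (SE 0.0612) over the 757 genes called in VEA 6.25 against saline. It was 0.830 to 0.895 on leaving out 1 library. Changes in CPM proportional to dose were not tested and stay open, since they give log2 ratios above 0.25 for genes that rise. The shared ethanol libraries are excluded as the whole cause, since a ratio with saline as the control of 3.12, over the 849 genes called in VEA 6.25 against ethanol, was 0.695 (SE 0.0428); both the control and the genes differ from the first ratio. PG animal 28 is excluded as the whole cause of the PG step, since 259 genes differed without it. A response near its ceiling at the lowest VEA dose may be a candidate explanation, and the delivered dose was not measured here.

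Club cell genes (5 to 7 of 11) and ciliated cell genes (5 to 8 of 15) fell after PG 1100 and the VEA doses, and none passed after PG 826. With an estimated correlation the ciliated list was lost in each of these comparisons (adjusted p = 0.0717 to 0.188) and the club list after PG 826 (0.173) and VEA 6.25 (0.0622). Less airway in the tissue taken is not settled by the spread of these falls. The 26 members did not fall by a common amount (Q per degree of freedom 3.27 after PG 1100 and 4.75 after VEA 12.5, where a common fall gives about 1). Less airway would give a common fall only if airway cells alone expressed these genes and both cell types were lost alike. Neither was tested. Dilution by other cells is not settled either. The club cell list fell below the surfactant list by a log2 difference of -1.05 (SE 0.208) after VEA 12.5 and -1.27 after PG 1100. But the surfactant list averages themselves rose, to 8.84 to 8.96 after VEA 12.5 against 8.53 to 8.61 after ethanol. After PG 1100 they were 9.19 to 9.34 against 8.55 to 8.70 after saline, so this list cannot measure dilution. Less airway, dilution, loss of airway cells and lower expression within them may each contribute and stay open.

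Other splits of the samples were tested for each count of called genes. For the 3 against 3 comparisons there are 10 splits, too few for a share under 0.05. Each number of splits given below includes the real split. As many genes as in the real split were called in 2 splits for PG 826 (real 20, highest other 139). Only the real split itself called as many for PG 1100 (1077, 6), VEA 3.12 (812, 2), VEA 6.25 (849, 2), VEA 12.5 (1430, 0) and PG 1100 against 826 (818, 16). At least as many genes as in the real split were called in 10 splits each for ethanol against saline (0, 2) and VEA 12.5 against 3.12 (0, 1). The PG 826 split with 139 genes put saline 6 with PG 23 and 25, and saline 8 and 10 with PG 22. Haemoglobin took 5.23% to 7.97% of counts on the side of saline 6 and 9.06% to 13.75% on the other. Whether this difference makes the 139 calls was not tested. For the difference between agents 9 of 100 splits gave as many genes (28, 1184), and for the trend 3 of 100 did (1042, 1301). These splits mix treated and control animals, or keep the ethanol animals together as the split with 1301 does, so they follow treatment and test neither a difference between agents nor an order of doses. With agents exchanged among treated and among control animals, 11 of 100 splits gave as many genes (28, 217), and with doses exchanged among the VEA animals 5 of 100 did (1042, 1131). Chance can therefore be excluded neither for the difference between agents nor for an order of the VEA doses.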
